A study of Mus musculus with 24 samples.

How the data were processed

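Total RNA of mouse primary keratinocytes (strain C57/BL6, per the labels) was measured on Affymetrix Mouse Gene ST arrays. The cells were cultured for 2 days before infection, and the RNA was extracted with TRIzol and cleaned on columns, per the labels' protocols. The authors deposited 1 table of log2 expression values for the 24 arrays, made with RMA (background correction, quantile normalization and probe summarisation) per the submitters' processing notes. The software and version used for RMA are not given in the sources used here. The log2 scale was checked on the deposited values, which lay between 2.27 and 14.8 with 0 missing. The sorted values of each array lay within 0.110 of their mean over arrays, and no further normalization was applied. Quantile normalization gives all arrays nearly the same distribution, so a change shared by most genes would not be seen, and a shift of a few genes is measured relative to the rest.

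The table held 34760 probe sets, of which 21640 had 1 gene symbol in the platform annotation, 1321 had several and 11799 had none listed. Only probe sets with 1 symbol were used for genes. Of the genes, 954 had several probe sets and were represented by the one with the highest mean over all arrays, which left 19937 genes tested, with no filter on dim genes. Entrez identifiers matched 19855 genes to a RefSeq gene table of GRCm38.p6, with 0 differing symbols. That table was used for names and for which genes neighbour each other, and no coordinates are given because the build behind the arrays is not given in the sources used here. Arrays were grouped by genotype, virus and ligand from the labels, 3 per group.

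A cell-means model of the 8 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual and 4.43 prior degrees of freedom), with no replicate block. From it 12 comparisons were taken: 8 between a pair of groups and 4 differences between such effects. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Adjusted p-values in the text are limma's. In all, 26 gene lists were fixed with 607 members, of which 568 were measured and 6 were matched through an older name. Of the lists, 25 were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation. The sex-linked list had 4 measured members, under the minimum of 5, and is given as values only. Some genes belong to several lists. The groups, comparisons, lists, rule for named genes and the alternatives to be tried were chosen before the data were examined.

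The genes named for a comparison were the 10 largest rises and the 10 largest falls among passing genes whose arrays did not overlap between the groups (for a difference, the 10 largest absolute values), up to 4 members per list with the largest absolute change in order of the list test, to about 30, and a fixed set of genes that may be given in any comparison. Predicted and unnamed transcripts were skipped in the top 10s. Nrg1, Ereg, Epgn and Lce3a in wild-type mock cells, Epcam and Pdgfra with Hras, Itga3 between genotypes, Tyrp1 for the GW0742 difference in Hras cells and the 9 genes that differed between genotypes in all 4 conditions fall outside this rule in part and were chosen after their values were seen. Hras, Cdkn1a and Areg were not analysed here.

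The alternatives chosen then were each array centred on its median, the 40% of genes with the lowest mean left out, trend and robust moderation, every probe set kept, only the arrays of the groups compared, a minimum fold of 1.5, the replicate number as a block, an estimated correlation for the lists, and leaving out each array in turn. Added after the data were seen were the model without the null Hras GW0742 group and array weights from limma, whose estimation stopped before it converged. The procedure was tested on simulated data for the GW0742 effect in wild-type mock cells over 19937 genes. It recovered 95% of 100 genes changed by 1.5-fold and 100% of 100 changed by 2-fold, with 7 false among 202 calls, 100% in the right direction and 0 calls in null mock cells. A shift of 0.3 given to the PPAR target list made that list pass and 1 other, where 2 lists share members with it. The draws were normal and independent between genes, and apart from the changed genes each gene had the same mean and SD in all groups. They therefore do not test false calls with correlated genes or with the wider spread of the null Hras GW0742 arrays. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and Python 3.11.15.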

Results

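Gene expression was measured in mouse primary keratinocytes, the main cells of the epidermis grown in culture, from wild-type mice and from mice lacking PPAR-beta (the product of Ppard, a nuclear receptor activated by fatty acids and also called PPAR-delta). Cells of each genotype were mock infected or infected with a retrovirus encoding activated Hras for 48 hours. They were then compared with or without 24 hours of 1 uM GW0742, a synthetic PPAR-beta agonist, against the vehicle DMSO. The 3 factors gave 8 groups of 3 arrays each, 24 arrays of total RNA in all. The median log2 expression of the arrays lay between 7.46 and 7.53, and the number of arrays limits the precision of every value. The first principal component held 66.5% of the variance and the second 9.42%. Changes are log2 differences ± standard error from a single limma model of all 24 arrays (n = 3 arrays per group), and 19937 genes were tested. The replicates are not stated to come from separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical.

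Ppard was measured first, because it was the targeted gene. Its mean log2 expression in DMSO was 11.19 ± 0.07 (SD, n = 3) in wild-type mock cells and 10.62 ± 0.02 in null mock cells. With GW0742 the values were 11.26 ± 0.04 and 10.71 ± 0.10. After Hras and DMSO they were 11.64 ± 0.04 in wild-type and 11.36 ± 0.02 in null cells, and after Hras and GW0742 they were 11.82 ± 0.02 and 11.36 ± 0.14. Ppard was lower in null than in wild-type cells by a log2 change of -0.57 ± 0.06 in mock cells (adjusted p = 1.53e-06) and -0.28 ± 0.06 in Hras cells (adjusted p = 0.00194). It was still well within the measured range in null cells. The deleted exons are not given in the sources used here, and a probe set outside the deleted part would check nothing about the knockout, so these levels do not by themselves test the genotype labels. Hras itself was not analysed here.

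The effect of the ligand was first measured in wild-type mock cells, where GW0742 raised genes of fatty acid use by up to 4.17 on the log2 scale. Angptl4, which encodes an inhibitor of lipoprotein lipase, rose by 4.17 ± 0.11 (adjusted p = 1.18e-16), and Pdk4, a kinase that restrains pyruvate dehydrogenase, rose by 4.14 ± 0.08 (adjusted p = 1.06e-18). The mean of Pdk4 went from 6.80 to 10.94 and that of Angptl4 from 7.48 to 11.65. Decr1 (1.98 ± 0.10), Acot1 (1.95 ± 0.08), Eci2 (1.45 ± 0.09), Cpt1a (1.30 ± 0.07) and Hadhb (1.23 ± 0.06), enzymes of fatty acid breakdown, rose as well. Plin2, a lipid droplet coat protein, rose by 1.13 ± 0.05. The cholesterol exporter Abca1 rose by 1.40 ± 0.07, the vasodilator peptide gene Adm by 1.73 ± 0.16, Acsbg1 by 1.66 ± 0.06 and Ces2f by 1.63 ± 0.10. Falls were smaller: the largest were those of Skint9 (-1.70 ± 0.18), Chil1 (-1.33 ± 0.13), Gabrp (-1.23 ± 0.15) and Serpinb3a (-1.14 ± 0.16).

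Of the 35 measured PPAR target genes, 17 rose, 0 fell and 18 did not pass (18 rose and 1 fell when adjusted over the list alone), with a median change of 0.27 (adjusted p = 1.15e-34). Mitochondrial fatty acid oxidation genes rose in 14 of 22 cases (14 rose and 1 fell when adjusted over the list alone, median 0.41, adjusted p = 2.67e-28). Cholesterol and sterol synthesis genes rose in 17 of 20 cases (17 adjusted over the list alone, median 0.34, adjusted p = 2.79e-33), among them Insig1 (0.71 ± 0.06), Lss (0.63 ± 0.06) and Cyp51 (0.57 ± 0.06). In the fatty acid synthesis list 6 of 21 genes rose (11 adjusted over the list alone, median 0.16, adjusted p = 1.11e-10). Scd1, a desaturase, rose by 0.59 ± 0.05 and the elongase Elovl6 by 0.46 ± 0.07. Among 7 EGF receptor ligands 3 rose (4 adjusted over the list alone, median 0.18, adjusted p = 2.5e-05): Nrg1, Ereg and Epgn. In the glycolysis and hypoxia list 6 of 27 genes rose (10 adjusted over the list alone, median 0.16, adjusted p = 4.47e-11, and adjusted p = 0.0744 with an estimated correlation). Bnip3 rose by 0.66 ± 0.12. The keratinocyte differentiation list had 1 gene higher (Lce3a), 2 lower (Flg2 at -0.79 ± 0.12 and Rptn at -0.89 ± 0.21) and 31 not passing (the same counts adjusted over the list alone, adjusted p = 0.83). Rptn passed with all arrays (adjusted p = 0.0198) and not without DMSO replicate 1 (adjusted p = 0.0726), 2 (0.0701) or 3 (0.0618) or without GW0742 replicate 1 (0.0830) or 3 (0.0841). None of the 16 basal keratinocyte genes passed (adjusted p = 0.44). Melanocyte markers, of which 0 of 12 passed and 3 fell when adjusted over the list alone, had a median of -0.17 (adjusted p = 2.45e-05, and adjusted p = 0.148 with an estimated correlation).

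In total 570 genes passed the test in wild-type mock cells, 250 higher and 320 lower with GW0742, and 99 of them changed by at least 1.5-fold. The count was 288 (147 higher, 141 lower) without DMSO replicate 2, 366 (194, 172) without DMSO replicate 3, 315 (184, 131) without GW0742 replicate 1 and 357 (169, 188) without GW0742 replicate 3. Without DMSO replicate 1 it was 393 (188, 205), so which direction held more genes turned with the array left out.

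In null mock cells GW0742 changed 0 genes by the limma test, with 1097 genes at an unadjusted p under 0.05 where 997 are expected by chance, and the lowest adjusted p was 0.0616. Refits without null mock DMSO replicate 1 and without null mock GW0742 replicate 1 gave 1 and 2 genes. Pdk4 measured 0.16 ± 0.08 (adjusted p = 0.903), Angptl4 0.03 ± 0.11 (adjusted p = 0.992), Cpt1a -0.07 ± 0.07 (adjusted p = 0.954) and Plin2 -0.04 ± 0.05 (adjusted p = 0.976). No member of any list passed over all genes. Adjusted over the list alone, 2 of the 16 basal keratinocyte genes were higher (list adjusted p = 0.0549). The median of the PPAR target genes was -0.02 (adjusted p = 0.393). Mitochondrial fatty acid oxidation (median -0.06, adjusted p = 0.0316) and interferon response genes (median -0.12, adjusted p = 0.000171) were lower as lists with 0 members passing in either adjustment. Both had an adjusted p = 0.811 with an estimated correlation.

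The difference of the GW0742 effect between genotypes, null minus wild-type, passed for 169 genes in mock cells, 57 with a positive and 112 with a negative difference. Angptl4 (-4.14 ± 0.15, adjusted p = 1.42e-13) and Pdk4 (-3.99 ± 0.12, adjusted p = 2.56e-15) differed most, followed by Acot1 (-2.12 ± 0.12), Decr1 (-2.05 ± 0.14), Adm (-1.90 ± 0.23) and Acsbg1 (-1.85 ± 0.09). The difference was positive for Skint9 (1.60 ± 0.25). It was negative and passing for 14 of 35 PPAR target genes (16 adjusted over the list alone, median -0.27, adjusted p = 2.45e-34). The same held for 11 of 22 mitochondrial fatty acid oxidation genes (14 adjusted over the list alone, median -0.46, adjusted p = 4.4e-32). For cholesterol and sterol synthesis it was negative for 13 of 20 genes (16 adjusted over the list alone, median -0.37, adjusted p = 1.07e-31). For fatty acid synthesis it was so for 3 of 21 (4 adjusted over the list alone, median -0.15, adjusted p = 6.2e-08). TGF-beta signalling and extracellular matrix genes differed in the positive direction as a list (median 0.13, adjusted p = 2.11e-05, and adjusted p = 0.182 with an estimated correlation), with Id2 passing at 0.40 ± 0.08 and 3 genes adjusted over the list alone. Melanocyte markers (median 0.14, 0 of 12 passing in either adjustment, adjusted p = 0.00159) and leukocyte and Langerhans cell markers (median 0.08, 0 of 22 passing and 1 adjusted over the list alone, adjusted p = 0.0357) also differed positively as lists. Both had an adjusted p = 0.248 with an estimated correlation. Of the 570 genes called in wild-type mock cells, 162 also passed this test of the difference. The count of 169 was 291 (125 positive, 166 negative) with only the arrays of these groups in the model and 260 (112, 148) with trend and robust moderation. A refit with one array left out gave between 114 and 162. The positive count fell to 27 without WT mock GW0742 replicate 1, 32 and 36 without WT mock DMSO replicates 2 and 3, 36 without WT mock GW0742 replicate 3, and 34 and 35 without null mock GW0742 replicates 2 and 3.

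**Figure D1:**
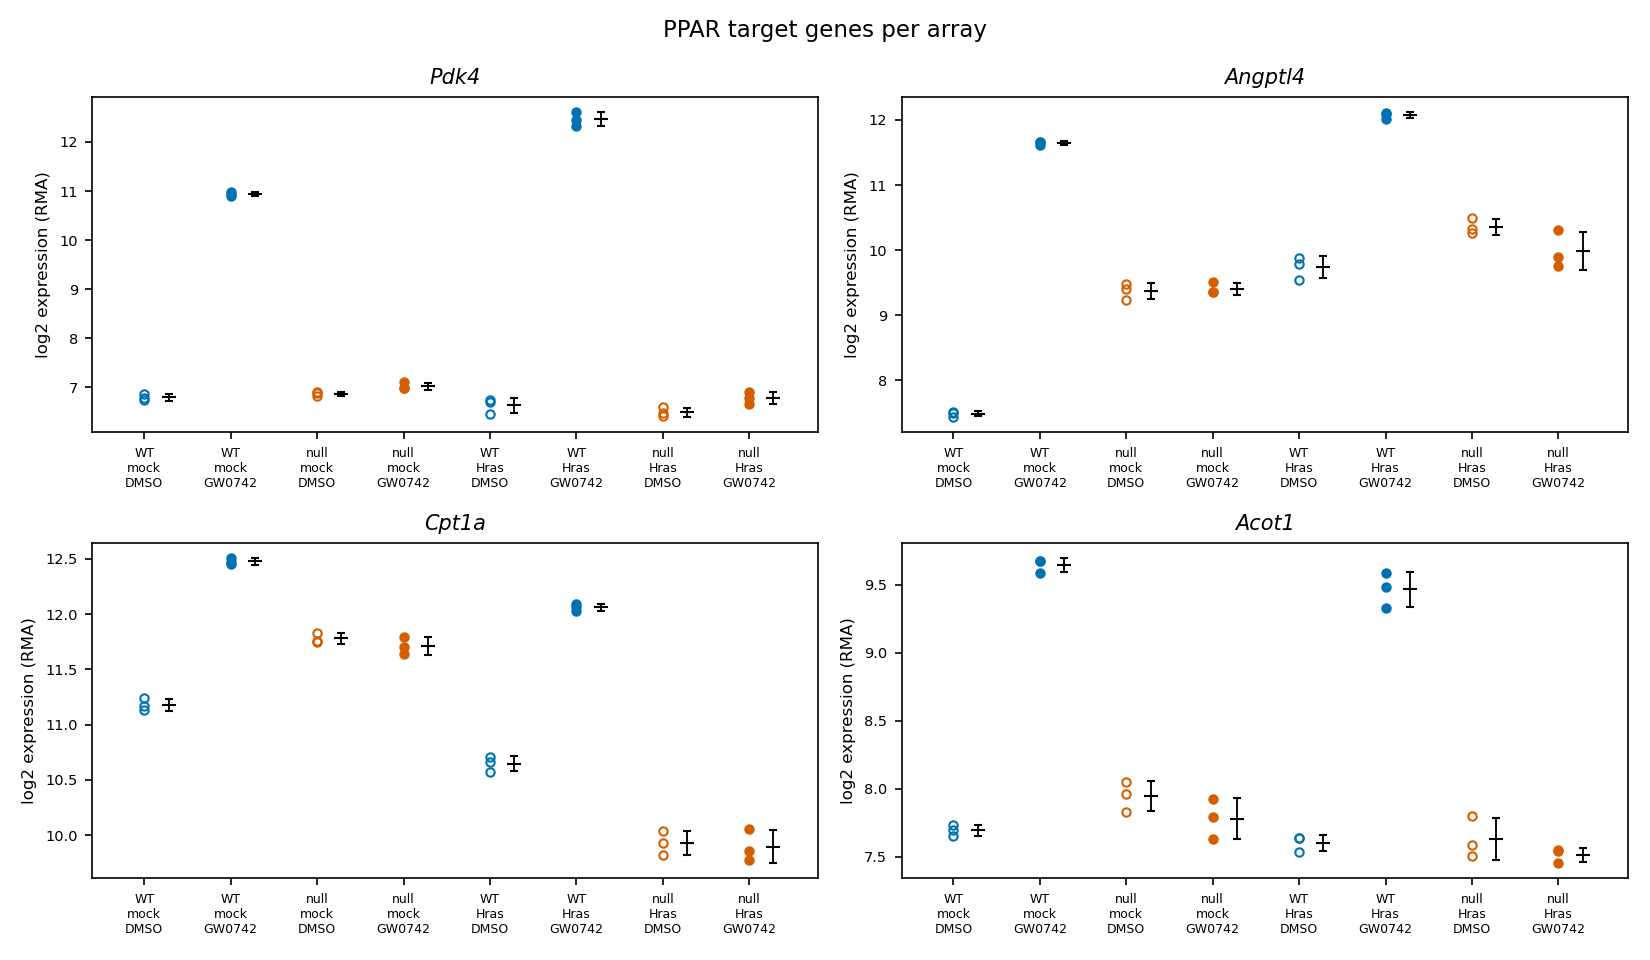
Log2 expression (RMA) of Pdk4, Angptl4, Cpt1a and Acot1 on each of the 24 arrays by group, with wild-type arrays in blue and null arrays in orange, DMSO as open and GW0742 as filled symbols, and black bars for the mean ± SD of 3 arrays. The Pdk4 mean went from 6.80 to 10.94 with GW0742 in wild-type mock cells and from 6.87 to 7.02 in null mock cells.

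In wild-type cells carrying Hras, GW0742 raised Pdk4 by 5.83 ± 0.08 (adjusted p = 1.03e-21), from a mean of 6.64 to 12.47. Angptl4 rose by 2.34 ± 0.11 from a DMSO level of 9.74. Serpinb9e (3.50 ± 0.19), Adm (3.24 ± 0.16), the phospholipases Pla2g4d (2.41 ± 0.15) and Pla2g4e (2.24 ± 0.15), Hilpda, a hypoxia-inducible lipid droplet gene (2.38 ± 0.05), and Rasgef1b (2.14 ± 0.14) rose too. The fatty acid carrier Fabp4 rose by 1.60 ± 0.11, Acot1 by 1.86 ± 0.08, Cpt1a by 1.42 ± 0.07, Plin2 by 1.32 ± 0.05 and Hadhb by 1.30 ± 0.06. Sostdc1, a secreted inhibitor of BMP and Wnt signals, fell the most (-1.31 ± 0.07, adjusted p = 8.3e-11), followed by Cp (-0.90 ± 0.16) and Lgr6 (-0.83 ± 0.13).

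PPAR target genes rose in 18 of 35 cases (19 adjusted over the list alone, median 0.28, adjusted p = 1.53e-30). Mitochondrial fatty acid oxidation genes rose in 13 of 22 (14 rose and 3 fell when adjusted over the list alone, median 0.45, adjusted p = 1.23e-19). Glycolysis and hypoxia genes rose in 22 of 27 cases (24 adjusted over the list alone, median 0.47, adjusted p = 7.82e-35), among them the oxygen sensor Egln3 at 1.49 ± 0.15. Of 17 epidermal lipid barrier genes 13 rose (14 rose and 1 fell when adjusted over the list alone, median 0.44, adjusted p = 9.31e-18). The lipoxygenase genes Alox12b (1.80 ± 0.17) and Aloxe3 (1.30 ± 0.17) and the lipase gene Pnpla1 (1.26 ± 0.16) were among them. EGF receptor ligands rose in 5 of 7 cases (5 adjusted over the list alone, median 0.48, adjusted p = 3.17e-11), with Hbegf at 0.95 ± 0.06. ERK pathway feedback and immediate targets rose in 11 of 28 (14 rose and 1 fell when adjusted over the list alone, median 0.14, adjusted p = 6.42e-09). In the keratinocyte differentiation list 12 genes rose, 1 fell and 21 did not pass (17 and 2 adjusted over the list alone, median 0.24, adjusted p = 8.12e-12, and adjusted p = 0.18 with an estimated correlation). Ivl, an envelope protein, rose by 0.74 ± 0.08. Cell cycle genes fell in 5 of 38 cases (7 fell and 1 rose when adjusted over the list alone, median -0.14, adjusted p = 1.26e-05, and adjusted p = 0.338 with an estimated correlation). The senescence and secretory list rose in 9 of 36 cases (10 adjusted over the list alone, median 0.04, adjusted p = 0.000234, and adjusted p = 0.18 with an estimated correlation).

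Melanocyte markers were higher in 1 of 12 cases (1 adjusted over the list alone, median 0.12, adjusted p = 0.0215, and adjusted p = 0.516 with an estimated correlation). The comparison passed 1219 genes, 890 higher and 329 lower, and 775 (619 higher, 156 lower) with only its own 6 arrays in the model. The lower count was 187 and 196 without DMSO replicates 1 and 2 and 157 without GW0742 replicate 3. With the ligand 137 genes rose in both mock and Hras wild-type cells against 11.2 expected for independent lists, and 56 fell in both against 5.28. Of genes called in both, 0 rose in mock and fell in Hras cells (4.13 expected), and 12 fell in mock and rose in Hras cells (14.3 expected).

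The ligand effect differed between Hras and mock wild-type cells for 492 genes, 408 of them with a more positive effect in Hras cells. Serpinb9e (2.82 ± 0.26), Mmp13, a collagenase (2.09 ± 0.31), Alox12b (1.94 ± 0.25), Pdk4 (1.69 ± 0.12) and Adm (1.51 ± 0.23) had the more positive effect with Hras. Angptl4 had the less positive one (-1.83 ± 0.15, adjusted p = 5.91e-07). The difference was positive for 11 of 27 glycolysis and hypoxia genes (16 adjusted over the list alone, median 0.31, adjusted p = 3.22e-14, and adjusted p = 0.0599 with an estimated correlation). It was positive for 6 of 17 lipid barrier genes (11 adjusted over the list alone, median 0.29, adjusted p = 9.35e-13, and adjusted p = 0.0816 with an estimated correlation). It was negative for 6 of 20 cholesterol and sterol synthesis genes (12 adjusted over the list alone, median -0.22, adjusted p = 9.35e-13). For EGF receptor ligands it was positive in 2 of 7 cases (3 adjusted over the list alone, median 0.15, adjusted p = 0.00014). For PPAR target genes as a list no difference passed (4 positive, 1 negative, 30 not passed, 5 and 1 adjusted over the list alone, median 0.01, adjusted p = 0.103). Melanocyte markers had a more positive ligand effect with Hras in 12 of 12 cases, 1 passing, Trpm1 (3 adjusted over the list alone, median 0.24, adjusted p = 6.63e-07, and adjusted p = 0.0816 with an estimated correlation). Leukocyte and Langerhans cell markers had 1 of 22 passing as positive (3 adjusted over the list alone, median 0.09, adjusted p = 0.034, and adjusted p = 0.264 with an estimated correlation). The count of 492 was 323 (37 less positive) without WT mock DMSO replicate 2, 311 (46) without WT mock GW0742 replicate 1 and 286 (42) without WT Hras GW0742 replicate 3. Against 84 with all arrays, the less positive were 54 without WT mock DMSO replicate 3 and 52 and 49 without WT mock GW0742 replicates 2 and 3.

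In null cells carrying Hras the PPAR target genes had a median change of -0.02 and a mean of 0.03 with GW0742 (adjusted p = 0.693, test direction upward). Of them 4 were higher, 2 lower and 29 not passing (5 and 3 adjusted over the list alone). Pdk4 measured 0.29 ± 0.08 (adjusted p = 0.0431). It missed the threshold with the arrays centred (0.27, adjusted p = 0.0613), without DMSO replicate 1 (0.25, adjusted p = 0.178) or 2 (0.27, adjusted p = 0.123) and without GW0742 replicate 3 (0.22, adjusted p = 0.193). Angptl4 measured -0.37 ± 0.11 (adjusted p = 0.0471). It missed the threshold with only the 6 arrays compared (adjusted p = 0.479), without DMSO replicate 1 (0.211), 2 (0.0867) or 3 (0.0530) and without GW0742 replicate 2 (0.222) or 3 (0.230). Cpt1a (-0.03 ± 0.07, adjusted p = 0.882) and Plin2 (-0.00 ± 0.05, adjusted p = 0.998) did not pass. Higher values included those of Pla2g4d (1.46 ± 0.15, adjusted p = 2.47e-05), the epithelial sodium channel subunits Scnn1g (1.42 ± 0.16) and Scnn1b (1.21 ± 0.16), Lce3a (1.36 ± 0.20) and the gap junction genes Gjb6 (1.29 ± 0.17) and Gjb2 (1.20 ± 0.15). Arc (-0.70 ± 0.13), Tlr3 (-0.68 ± 0.13) and Trpv6 (-0.59 ± 0.10) were among the lower genes.

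These values rest on the spread shared by all 8 groups. In that model 1001 genes passed, 700 higher and 301 lower, while with only the 6 arrays compared 0 passed by limma, and the lowest adjusted p among the named genes was 0.0507 for Lce3a. The null Hras GW0742 arrays had the widest spread, a median residual SD of 0.122 against 0.0647 to 0.0798 in the other groups. The count was 393 (64 lower) without GW0742 replicate 2, 601 (133) without DMSO replicate 1 and 2539 (1306) without GW0742 replicate 1. The lower count was 163 without DMSO replicate 2 and 109 without GW0742 replicate 3.

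In the same model keratinocyte differentiation genes passed as higher in 19 of 34 cases (24 adjusted over the list alone, median 0.42, adjusted p = 6.45e-25, and adjusted p = 0.0549 with an estimated correlation). Lipid barrier genes were higher in 12 of 17 cases (14 higher and 1 lower when adjusted over the list alone, median 0.39, adjusted p = 6.8e-13, and adjusted p = 0.0659 with an estimated correlation). Glycolysis and hypoxia genes were higher in 17 of 27 cases (23 adjusted over the list alone, median 0.35, adjusted p = 1.76e-22), with Egln3 at 1.17 ± 0.15, Adm at 1.07 ± 0.16 and Bnip3 at 0.81 ± 0.12. Melanocyte markers were higher in 8 of 12 cases (10 adjusted over the list alone, median 0.30, adjusted p = 5.59e-12). Cholesterol and sterol synthesis genes were lower in 7 of 20 cases (14 adjusted over the list alone, median -0.18, adjusted p = 1.94e-12), including Insig1 at -0.44 ± 0.06. Among the p53 target genes 4 of 26 were lower (2 higher and 8 lower when adjusted over the list alone, median -0.08, adjusted p = 0.00194, and adjusted p = 0.13 with an estimated correlation). NRF2 and glutathione genes had 1 of 23 lower (1 higher and 3 lower when adjusted over the list alone, median -0.07, adjusted p = 0.012, and adjusted p = 0.371 with an estimated correlation). With GW0742 359 genes passed as higher in both wild-type and null Hras cells against 31.2 expected for independent lists, and 30 as lower in both against 4.97. In opposite directions, 8 were higher in wild-type and lower in null cells (13.4 expected) and 5 the reverse (11.6 expected).

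The GW0742 effect differed between the genotypes in Hras cells for 344 genes, 103 positive and 241 negative (63 and 269 of 332 with the arrays centred). Pdk4 (-5.54 ± 0.12, adjusted p = 3.31e-18), Serpinb9e (-2.87 ± 0.26), Angptl4 (-2.71 ± 0.15), Hilpda (-2.26 ± 0.08), Adm (-2.17 ± 0.23) and Acot1 (-1.98 ± 0.12) had a less positive effect in null cells, and Rptn a more positive one (1.69 ± 0.30). The difference was negative for 15 of 35 PPAR target genes (18 adjusted over the list alone, median -0.28, adjusted p = 2.53e-33). The same direction passed for 12 of 22 mitochondrial fatty acid oxidation genes (15 adjusted over the list alone, median -0.50, adjusted p = 6.36e-29) and 8 of 20 cholesterol and sterol synthesis genes (18 adjusted over the list alone, median -0.26, adjusted p = 1.59e-20). EGF receptor ligands differed in 2 of 7 cases, Ereg (-0.82 ± 0.13) and Hbegf (-0.66 ± 0.08), with 3 adjusted over the list alone, a median of -0.36 and an adjusted p = 4.4e-07. ERK targets differed negatively in 7 of 28 cases (1 positive and 11 negative when adjusted over the list alone, median -0.10, adjusted p = 1.2e-06), with Fos at -1.40 ± 0.16. Fatty acid synthesis genes differed in 5 of 21 cases (1 positive and 6 negative when adjusted over the list alone, median -0.12, adjusted p = 8.58e-06). The chemokines Cxcl1 (-1.44 ± 0.19) and Cxcl2 (-1.40 ± 0.23) were among 7 of 36 senescence and secretory genes with a negative difference (10 adjusted over the list alone, median -0.09, adjusted p = 7.89e-06, and adjusted p = 0.0965 with an estimated correlation). For keratinocyte differentiation genes the difference did not pass as a list (4 positive, 30 not passed, 6 positive and 3 negative adjusted over the list alone, adjusted p = 0.0577). Melanocyte markers had a more positive ligand effect in null Hras cells in 12 of 12 cases, 1 passing, Tyrp1 (3 adjusted over the list alone, median 0.17, adjusted p = 3.34e-05, and adjusted p = 0.139 with an estimated correlation). Hair follicle and sebocyte markers had 1 of 20 passing as positive (3 adjusted over the list alone, median 0.10, adjusted p = 0.0169, and adjusted p = 0.0965 with an estimated correlation). The count of 344 was 103 (14 positive, 89 negative) with only the arrays of these groups in the model and 651 (214, 437) without null Hras GW0742 replicate 1. The positive count was 59 and 63 without WT Hras DMSO replicates 2 and 3, 68 without null Hras DMSO replicate 3 and 54 without null Hras GW0742 replicate 2.

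**Figure D2:**
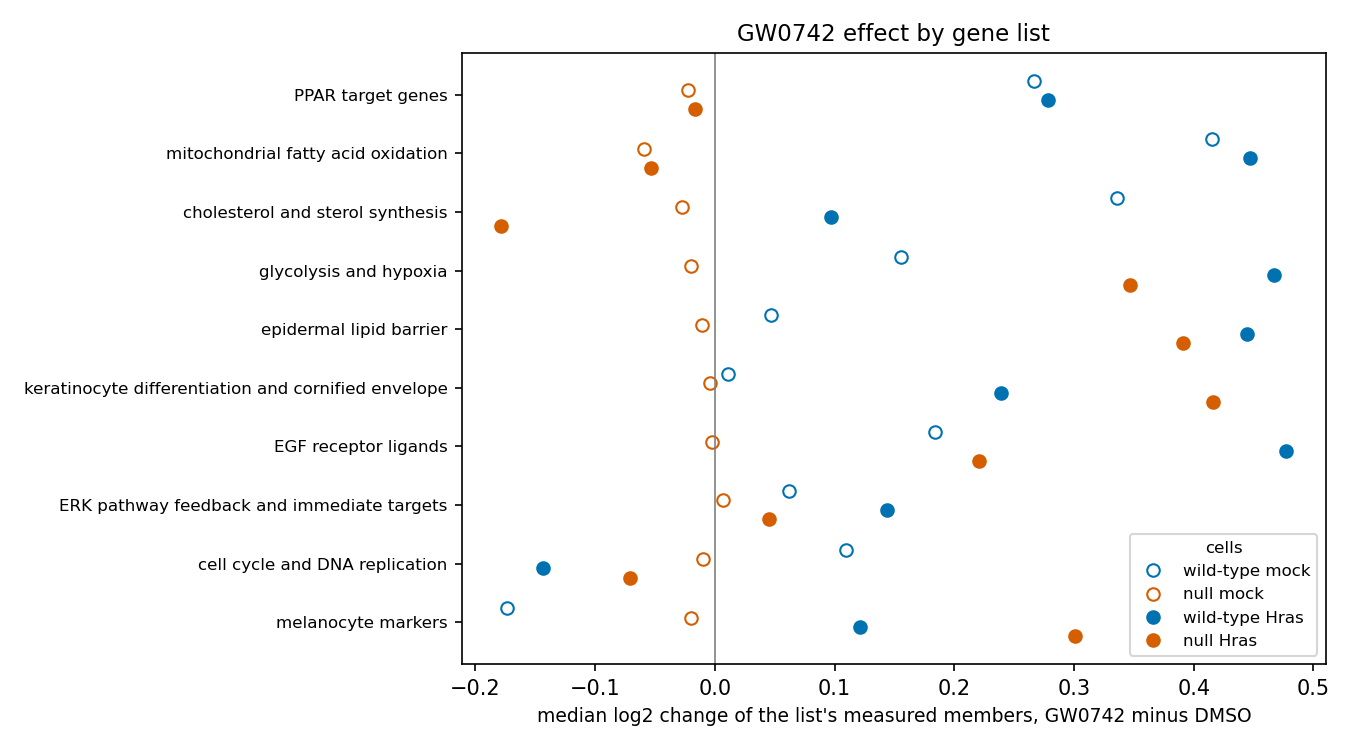
Median log2 change with GW0742 against DMSO over the measured members of 10 gene lists, in wild-type (blue) and null (orange) cells, mock (open) and Hras (filled). The PPAR target list lay at 0.27 and 0.28 in wild-type mock and Hras cells and at -0.02 in both kinds of null cells.

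The effect of the retrovirus encoding activated Hras was measured in DMSO, against mock infected cells. The labels name no virus without Hras, so infection and Hras cannot be told apart in what is called the Hras effect. In wild-type cells the suprabasal keratins Krt1 and Krt10, markers of early differentiation, fell by 5.80 ± 0.13 (adjusted p = 1.71e-18) and 4.85 ± 0.09 (adjusted p = 1.44e-19). The simple epithelial keratins Krt18 and Krt8 rose by 5.17 ± 0.14 and 4.23 ± 0.16. The platelet chemokine precursor Ppbp (5.65 ± 0.17), the prolactin family gene Prl2c5 (5.41 ± 0.22), the potassium channel Kcnn4 (4.92 ± 0.10), the claudin Cldn7 (3.99 ± 0.18) and the cytokine Csf2 (3.83 ± 0.22) rose. Aadacl2 (-4.45 ± 0.12), Serpinb3a (-4.43 ± 0.16), Them5 (-4.32 ± 0.11), Dapl1 (-4.11 ± 0.13) and Pou2f3 (-3.81 ± 0.05) fell. Of the fixed genes, Fosl1 (1.40 ± 0.09), the ERK phosphatase gene Dusp6 (1.31 ± 0.07), Cdkn2a, which encodes p16 and p19 (1.26 ± 0.10), and Angptl4 (2.25 ± 0.11) rose. The Ras exchange factor gene Rasgrp1 (-1.76 ± 0.08) and Rxra (-0.70 ± 0.05) fell. Ppard rose by 0.46 ± 0.06 (adjusted p = 2.17e-06).

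Keratinocyte differentiation genes fell in 24 of 34 cases and rose in 3 (24 and 4 adjusted over the list alone, median -1.20, adjusted p = 4.09e-11, and adjusted p = 0.166 with an estimated correlation). Lor (-2.53 ± 0.15), Tgm5 (-2.66 ± 0.12) and Calm4 (-2.73 ± 0.14) were among them. Unfolded protein response genes rose in 31 of 37 cases and fell in 1 (the same counts adjusted over the list alone, median 0.31, adjusted p = 9.2e-09, and adjusted p = 0.166 with an estimated correlation). The senescence and secretory list rose in 21 of 36 cases and fell in 4 (the same counts adjusted over the list alone, median 0.43, adjusted p = 6.15e-07, and adjusted p = 0.0911 with an estimated correlation). Cell cycle genes rose in 21 of 38 cases and fell in 1 (22 and 1 adjusted over the list alone, median 0.26, adjusted p = 3.57e-05, and adjusted p = 0.24 with an estimated correlation). In the simple epithelial keratin and plasticity list 8 genes rose and 7 fell (8 and 7 adjusted over the list alone, median 0.03, adjusted p = 0.232). Basal keratinocyte genes had 4 higher and 7 lower of 16 (5 and 8 adjusted over the list alone, adjusted p = 0.47), and Krt14 changed by -0.18 ± 0.04 (adjusted p = 0.000544).

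Markers of other cells moved with Hras. Fibroblast markers fell in 15 of 16 cases (15 adjusted over the list alone, median -1.42, adjusted p = 6.89e-12). Postn (-2.04 ± 0.10), Pdgfrb (-2.04 ± 0.07) and Thy1 (-2.03 ± 0.13) fell the most of them, and the collagen-binding gene Aspn fell by 4.12 ± 0.20. All 12 melanocyte markers fell (12 adjusted over the list alone, median -0.93, adjusted p = 1.52e-10, and adjusted p = 0.0624 with an estimated correlation), for example Mlana (-1.36 ± 0.08) and Dct (-1.21 ± 0.09). Leukocyte and Langerhans cell markers fell in 7 of 22 cases and rose in 1, Epcam (8 and 1 adjusted over the list alone, median -0.11, adjusted p = 0.0244, and adjusted p = 0.222 with an estimated correlation). Hair follicle and sebocyte markers fell in 10 of 20 cases and rose in 3 (10 and 3 adjusted over the list alone, median -0.14, adjusted p = 0.0269, and adjusted p = 0.166 with an estimated correlation). Endothelial markers did not pass as a list (4 higher, 2 lower, 6 not passed, the same counts of calls adjusted over the list alone, adjusted p = 0.413). Neither did the skeletal muscle and adipocyte markers (3 higher, 13 not passed, 3 adjusted over the list alone, adjusted p = 0.279). Nor did the Ras exchange factor and PI3K-AKT list (11 higher, 7 lower, 8 not passed, 12 and 7 adjusted over the list alone, adjusted p = 0.514). In all 7454 genes passed, 3671 higher and 3783 lower with Hras, and 2198 of them changed by at least 1.5-fold.

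**Figure D3:**
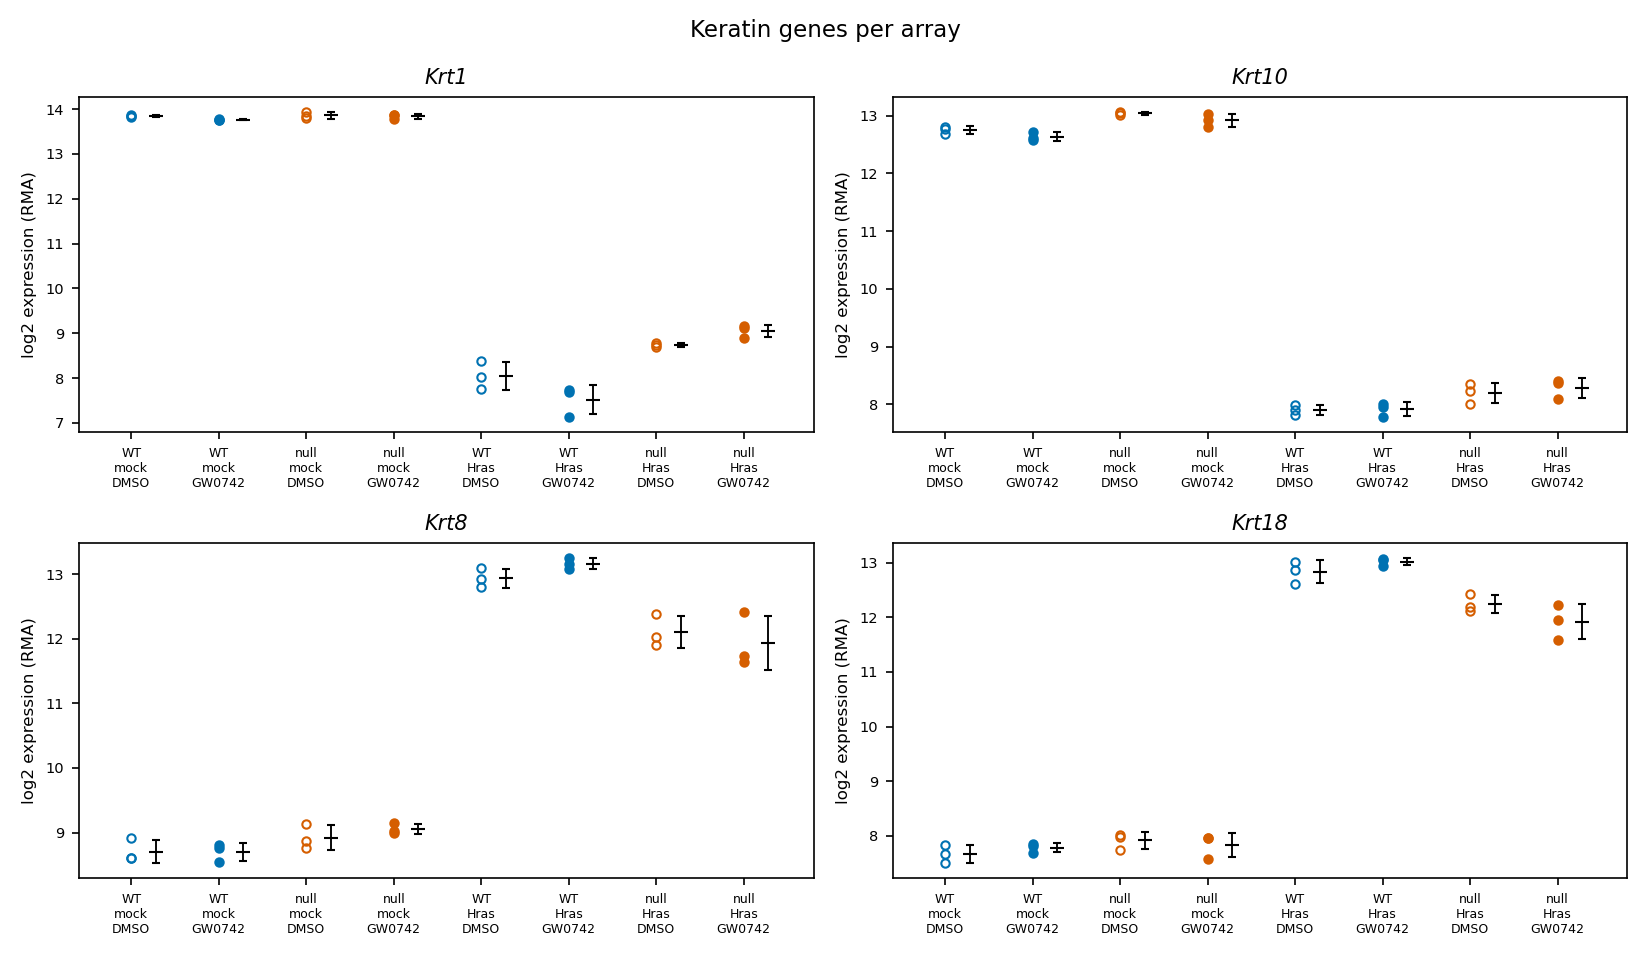
Log2 expression (RMA) of Krt1, Krt10, Krt8 and Krt18 on each of the 24 arrays by group, with wild-type in blue and null in orange, DMSO as open and GW0742 as filled symbols, and black bars for the mean ± SD of 3 arrays. In DMSO the Krt1 mean went from 13.85 to 8.05 with Hras in wild-type cells and from 13.86 to 8.73 in null cells, and the Krt18 mean from 7.67 to 12.83 and from 7.91 to 12.24.

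Null cells also lost the suprabasal keratins with Hras (Krt1 -5.13 ± 0.13, Krt10 -4.85 ± 0.09) and gained Krt18 (4.33 ± 0.14) and Krt8 (3.19 ± 0.16). Ppbp (5.91 ± 0.17), Prl2c5 (5.61 ± 0.22), Kcnn4 (4.34 ± 0.10) and the cytokine Il1a (3.77 ± 0.09) rose, and Sema3d (-4.77 ± 0.11), Dapl1 (-4.74 ± 0.13) and Serpinb3a (-4.56 ± 0.16) fell. Unfolded protein response genes rose in 36 of 37 cases (36 adjusted over the list alone, median 0.85, adjusted p = 5.62e-23), led by Derl3 (2.52 ± 0.17), Nupr1 (1.88 ± 0.06) and Trib3 (1.80 ± 0.08). Glycolysis and hypoxia genes rose in 23 of 27 cases and fell in 1 (the same counts adjusted over the list alone, median 0.62, adjusted p = 3.31e-13, and adjusted p = 0.0611 with an estimated correlation). Slc16a3, a lactate exporter, rose by 2.10 ± 0.08 and Vegfa by 1.70 ± 0.06. ERK targets rose in 19 of 28 cases and fell in 4 (20 and 4 adjusted over the list alone, median 0.70, adjusted p = 2.2e-08). EGF receptor ligands rose in 6 of 7 (6 adjusted over the list alone, median 1.55, adjusted p = 2.6e-07). Interferon response genes fell in 26 of 32 cases and rose in 1 (27 and 1 adjusted over the list alone, median -0.69, adjusted p = 4.96e-10, and adjusted p = 0.069 with an estimated correlation). Usp18 (-3.43 ± 0.24) and Xaf1 (-2.67 ± 0.16) fell the most of them. Fibroblast markers fell in 11 of 16 cases and rose in 1, Pdgfra (the same counts adjusted over the list alone, median -0.59, adjusted p = 7.52e-05, and adjusted p = 0.0667 with an estimated correlation). All 12 melanocyte markers fell (12 adjusted over the list alone, median -0.65, adjusted p = 1.97e-07, and adjusted p = 0.0667 with an estimated correlation). Hair follicle and sebocyte markers fell in 10 of 20 cases and rose in 4 (the same counts adjusted over the list alone, median -0.25, adjusted p = 0.00832, and adjusted p = 0.0667 with an estimated correlation). The Y-linked genes Eif2s3y (-1.17), Kdm5d (-0.96) and Uty (-0.75) fell and Xist, expressed from the inactive X chromosome, rose (0.39) in the same comparison, while none of the 4 passed with Hras in wild-type cells. The null mock and null Hras cultures may therefore have differed in makeup, which cannot be told apart from the Hras effect in null cells. In null cells 8119 genes passed, 4029 higher and 4090 lower. Across the genotypes 2541 genes rose with Hras in both against 742 expected for independent lists, and 2746 fell in both against 776. In opposite directions, 126 rose in wild-type and fell in null cells (753 expected) and 115 fell in wild-type and rose in null cells (764 expected).

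The difference of the Hras effect between genotypes, null minus wild-type, passed for 3342 genes, 1665 positive and 1677 negative (1961 and 1307 of 3268 with the arrays centred). It was positive for 29 of 37 unfolded protein response genes (31 adjusted over the list alone, median 0.49, adjusted p = 7.83e-23). Among them were Derl3 at 1.62 ± 0.24, Trib3 at 1.23 ± 0.11, the stress transcription factor gene Ddit3 at 0.95 ± 0.12, Atf3 at 0.94 ± 0.11, Chac1 at 0.92 ± 0.13, the chaperone gene Hspa5 at 0.52 ± 0.08 and Atf4 at 0.48 ± 0.07. ERK targets differed positively in 19 of 28 cases (22 positive and 1 negative adjusted over the list alone, median 0.43, adjusted p = 7.06e-12). EGF receptor ligands did so in 6 of 7 cases (6 adjusted over the list alone, median 0.64, adjusted p = 6.27e-08), with Epgn at 1.93 ± 0.18 and Ereg at 1.22 ± 0.13. Keratinocyte differentiation genes differed positively in 20 of 34 cases and negatively in 1 (24 and 1 adjusted over the list alone, median 0.61, adjusted p = 6.91e-13, and adjusted p = 0.185 with an estimated correlation), with Lce1b at 2.42 ± 0.23. TGF-beta and matrix genes differed negatively in 17 of 26 cases and positively in 1 (18 and 1 adjusted over the list alone, median -0.42, adjusted p = 2.55e-09, and adjusted p = 0.067 with an estimated correlation). Ccn2 differed by -1.04 ± 0.13 and Tgfb2 by -0.78 ± 0.10. The largest negative differences were those of Gabrp (-3.36 ± 0.21), Sorbs2 (-3.21 ± 0.17) and Il3 (-3.06 ± 0.33), and the largest positive ones Defb4 (2.87 ± 0.33), Kctd4 (2.73 ± 0.27) and Aspn (2.67 ± 0.28). Gabrp rose by 1.16 in wild-type cells and fell in null cells (-2.20), as did Sorbs2 (1.08 and -2.13) and Cdkn2b (0.51 and -0.37, difference -0.88 ± 0.15). Krt8 (-1.04 ± 0.22), Krt18 (-0.84 ± 0.20) and Cdkn2a (-0.58 ± 0.14) had a less positive Hras effect in null cells. Fibroblast markers differed positively in 11 of 16 cases and negatively in 2 (13 and 2 adjusted over the list alone, median 0.80, adjusted p = 4.38e-10). Melanocyte markers differed positively in 4 of 12 cases (5 adjusted over the list alone, median 0.27, adjusted p = 0.00288, and adjusted p = 0.294 with an estimated correlation). In the same comparison the median difference of the 4 sex-linked genes was -0.80, with Xist positive and the Y-linked genes negative. A different makeup of the cultures therefore cannot be told apart from a different response to Hras by genotype. Whether both genotypes carried Hras equally was not checked.

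**Figure D4:**
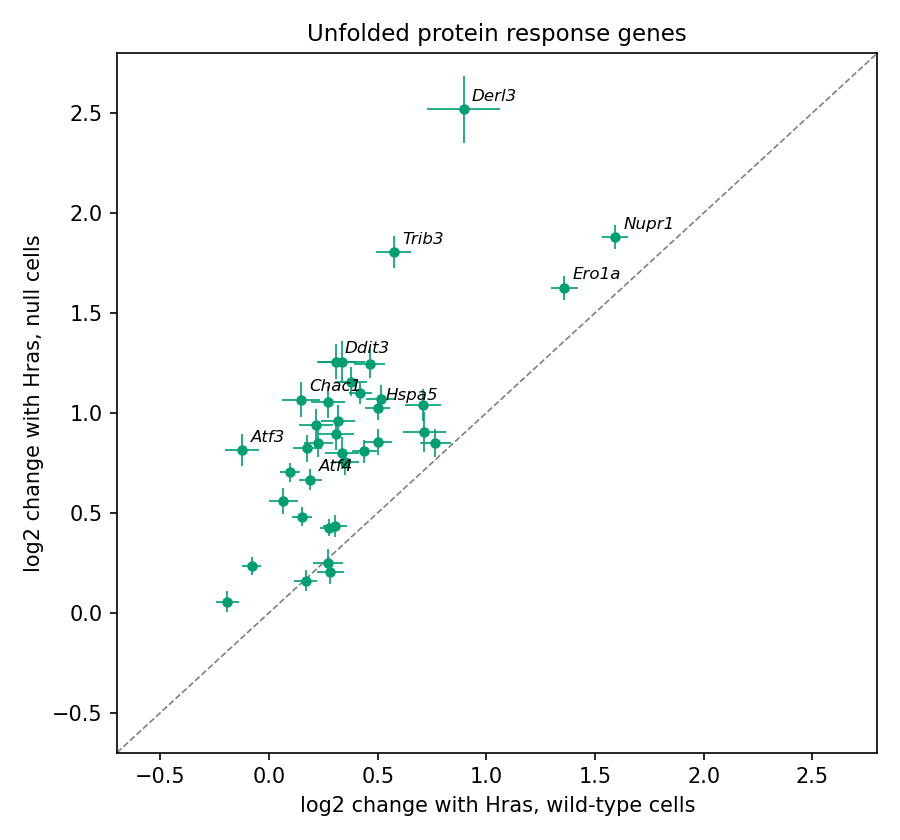
Log2 change with Hras of the 37 measured unfolded protein response genes in wild-type (x axis) and null (y axis) cells in DMSO, each point a gene with ± standard error and the dashed line marking equal change. The change was more positive in null cells for 34 of the 37 genes.

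In DMSO, null mock cells had lower levels of many cell cycle genes and ERK targets than wild-type mock cells. Cell cycle genes were lower in null cells in 20 of 38 cases (29 adjusted over the list alone, median -0.22, adjusted p = 8.6e-18). Mcm6 (-0.70 ± 0.07), Aurkb (-0.41 ± 0.06) and the proliferation marker Mki67 (-0.34 ± 0.07) were lower. ERK targets were lower in 14 of 28 cases (15 adjusted over the list alone, median -0.20, adjusted p = 2.85e-14). They included Etv5 (-0.80 ± 0.10), Ccnd1 (-0.69 ± 0.08), Spry4 (-0.63 ± 0.08) and Dusp6 (-0.34 ± 0.07). EGF receptor ligands were lower in 3 of 7 cases (5 adjusted over the list alone, median -0.22, adjusted p = 0.00015), with Hbegf at -0.31 ± 0.06. Angptl4 (1.89 ± 0.11, adjusted p = 1.38e-10), Cpt1a (0.60 ± 0.07) and Cdkn2b (0.64 ± 0.11) were higher. Pdk4 (0.07 ± 0.08, adjusted p = 0.684) and Plin2 (0.01 ± 0.05, adjusted p = 0.964) did not pass. Spon2 (2.17 ± 0.07), Sorbs2 (1.70 ± 0.12), Atp10d (1.45 ± 0.06) and the oxidase gene Nox4 (1.30 ± 0.14) were also higher. Ublcp1 (-3.35 ± 0.19), Aspn (-2.25 ± 0.20), Rptn (-1.82 ± 0.21), Klk9 (-1.80 ± 0.13), the amino acid transporter gene Slc1a5 (-1.78 ± 0.09) and Mcam (-1.78 ± 0.07) were lower.

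Cholesterol and sterol synthesis genes were higher in null mock cells in 12 of 20 cases (13 adjusted over the list alone, median 0.23, adjusted p = 2.19e-09). Fatty acid synthesis genes were higher in 6 of 21 (10 adjusted over the list alone, median 0.14, adjusted p = 7.77e-05). Interferon response genes were higher in 12 of 32 cases (17 adjusted over the list alone, median 0.33, adjusted p = 2e-08, and adjusted p = 0.114 with an estimated correlation). Keratinocyte differentiation genes were lower in 11 of 34 cases and higher in 3 (14 and 4 adjusted over the list alone, median -0.21, adjusted p = 2.9e-06, and adjusted p = 0.333 with an estimated correlation). Basal keratinocyte genes were higher in 4 of 16 cases and lower in 1, the integrin gene Itga3 (7 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.0191, and adjusted p = 0.114 with an estimated correlation). Fibroblast markers were lower in 12 of 16 cases and higher in 1 (13 and 2 adjusted over the list alone, median -0.60, adjusted p = 5.81e-15), with Pdgfrb at -1.08 ± 0.07 and Col1a2 at -0.96 ± 0.08. Melanocyte markers were lower in 6 of 12 cases (9 adjusted over the list alone, median -0.28, adjusted p = 7.39e-08, and adjusted p = 0.0534 with an estimated correlation). In the same comparison the Y-linked genes Eif2s3y (0.65), Uty (0.33) and Kdm5d (0.31) were higher and Xist (-0.31) was lower in null cells, all 4 passing. In all 2076 genes passed, 974 higher (636 without WT mock DMSO replicate 1) and 1102 lower in null cells, and 334 of them differed by at least 1.5-fold.

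With Hras and DMSO, single genes of the unfolded protein response and of keratinocyte differentiation were higher in null than in wild-type cells. Of the lists called, 1 (EGF receptor ligands) also passed with an estimated correlation. Unfolded protein response genes were higher in 28 of 37 cases (29 adjusted over the list alone, median 0.34, adjusted p = 3.08e-19, and adjusted p = 0.083 with an estimated correlation). Derl3 differed by 1.53 ± 0.17, Ppp1r15a by 1.31 ± 0.10, Sdf2l1 by 0.80 ± 0.08 and Atf3 by 0.74 ± 0.08. Keratinocyte differentiation genes were higher in 18 of 34 cases and lower in 3 (22 and 3 adjusted over the list alone, median 0.46, adjusted p = 2.24e-07, and adjusted p = 0.372 with an estimated correlation). Klk5 differed by 1.42 ± 0.18, Lce1b by 1.00 ± 0.16, Lor by 0.83 ± 0.15 and Krt1 by 0.68 ± 0.13. Glycolysis and hypoxia genes were higher in 19 of 27 cases (22 higher and 1 lower when adjusted over the list alone, median 0.30, adjusted p = 4.99e-10, and adjusted p = 0.143 with an estimated correlation). EGF receptor ligands were higher in 5 of 7 (5 adjusted over the list alone, median 0.33, adjusted p = 7.34e-06). TGF-beta and matrix genes were lower in 14 of 26 cases and higher in 2 (17 and 2 adjusted over the list alone, median -0.21, adjusted p = 4.64e-07, and adjusted p = 0.143 with an estimated correlation). Krt8 (-0.83 ± 0.16), Krt18 (-0.59 ± 0.14), Cpt1a (-0.72 ± 0.07), Rasgrp1 (-0.69 ± 0.08) and Rxra (-0.27 ± 0.05) were lower in null cells. So were Mcam (-3.23 ± 0.07), Il3 (-3.01 ± 0.23), Ublcp1 (-2.81 ± 0.19), the peptide transporter gene Slc15a2 (-2.50 ± 0.13) and Mid1 (-2.45 ± 0.05). Spon2 (2.20 ± 0.07), Dhdh (1.99 ± 0.12), Atp10d (1.94 ± 0.06) and the collagenase genes Mmp1b (1.80 ± 0.16) and Mmp1a (1.68 ± 0.17) were higher. In all 3871 genes passed, 2012 higher and 1859 lower in null cells (2603 and 1464 of 4067 with the arrays centred).

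The fibroblast list did not pass between genotypes with Hras (7 higher, 2 lower, 7 not passed, the same counts of calls adjusted over the list alone, median 0.13, adjusted p = 0.0821). Neither did the melanocyte list (1 lower, 11 not passed, 1 adjusted over the list alone, adjusted p = 0.536). Here Eif2s3y (-0.43), Kdm5d (-0.50) and Uty (-0.46) were lower in null cells, and Xist measured 0.13 (adjusted p = 0.175). The genotype differences in mock and in Hras cells had a correlation of -0.02 across genes, which are not independent replicates. In both kinds of cells 173 genes were higher in null than in wild-type (98.3 expected for independent lists) and 238 lower (103 expected), while 228 were higher in mock and lower in Hras cells (90.8 expected) and 242 the reverse (111 expected).

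**Figure D5:**
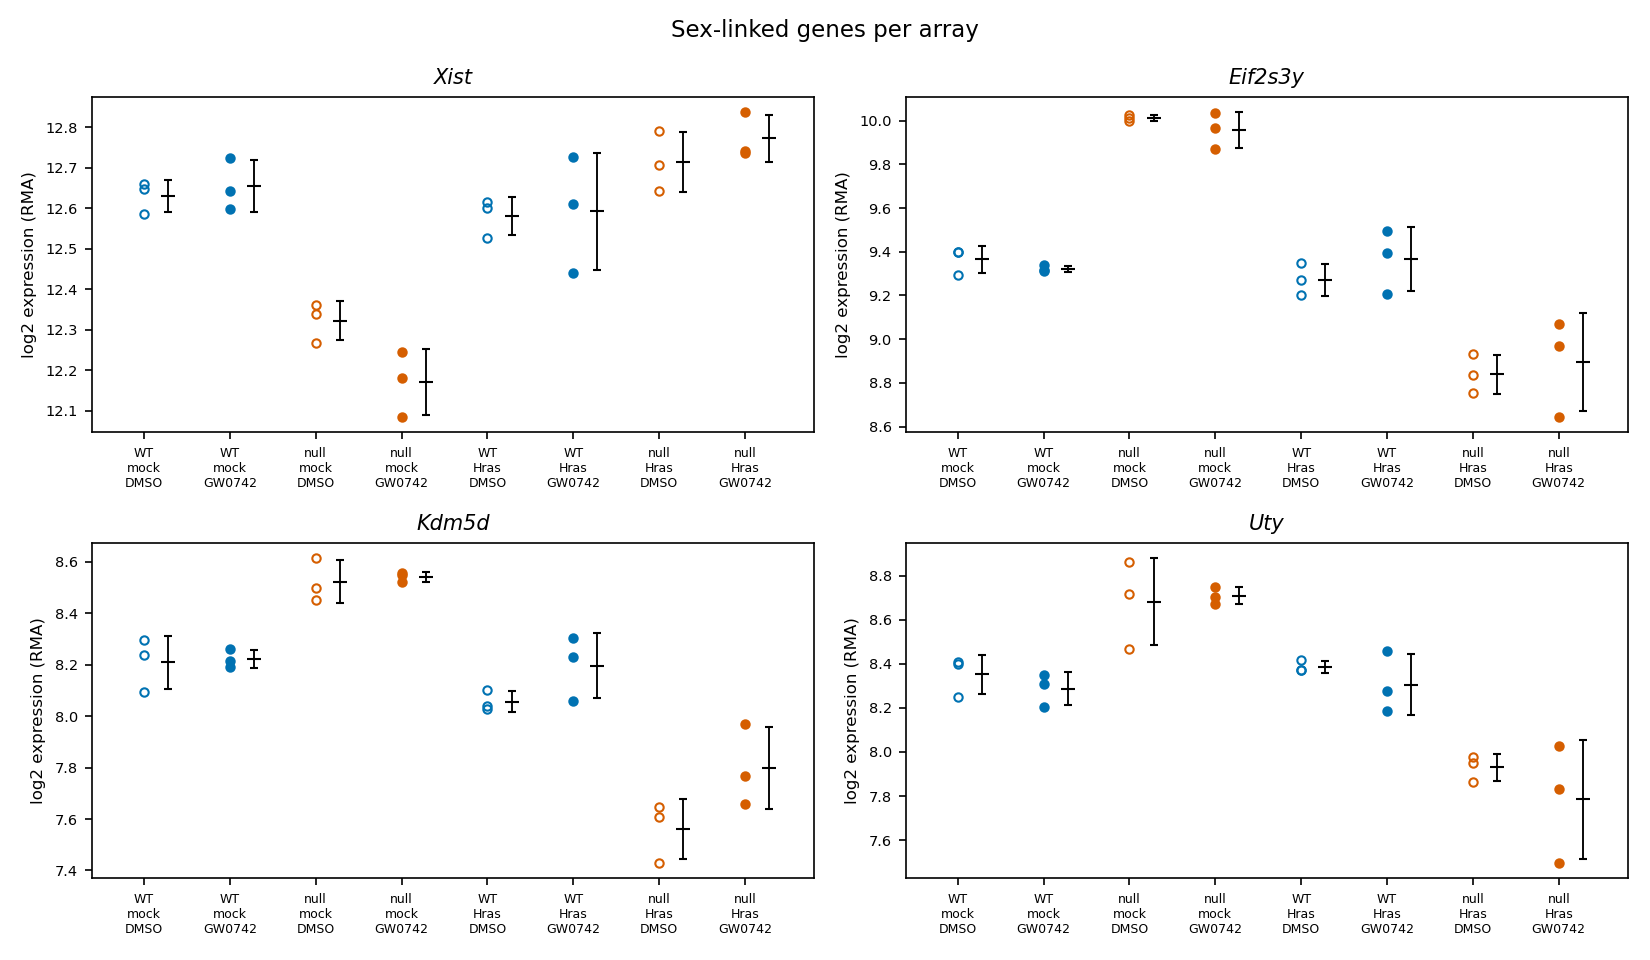
Log2 expression (RMA) of Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 24 arrays by group, with wild-type in blue and null in orange, DMSO as open and GW0742 as filled symbols, and black bars for the mean ± SD of 3 arrays. The Eif2s3y mean in DMSO was 9.36 in wild-type mock, 10.01 in null mock, 9.27 in wild-type Hras and 8.84 in null Hras cells.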

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

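The test of remaining receptor function in null cells was chosen after the result was seen, and so were the model without the null Hras GW0742 group and the array weights. The following results differed between 2 groups in a test of the difference itself.

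In mock cells the GW0742 effect differed between genotypes for 169 genes, with Angptl4 at -4.14, Pdk4 at -3.99 and Acot1 at -2.12 and list medians of -0.27 for PPAR targets, -0.46 for mitochondrial fatty acid oxidation, -0.37 for cholesterol and sterol synthesis and -0.15 for fatty acid synthesis. In 2 of 100 drawn splits, with the ligand labels regrouped and the real one included, as many genes passed, a share under 0.05. The highest other split gave 176. The splits regroup the labels of both effects, so they set the count against no effect in either genotype. They cannot test whether 2 real effects are equal. In Hras cells the difference passed for 344 genes, with Pdk4 at -5.54, Serpinb9e at -2.87 and Angptl4 at -2.71 and list medians of -0.28 for PPAR targets, -0.50 for mitochondrial fatty acid oxidation, -0.26 for cholesterol and sterol synthesis, -0.36 for EGF receptor ligands, -0.10 for ERK targets and -0.12 for fatty acid synthesis. As many genes passed in 8 of 100 splits, the highest other giving 1903, so over all splits chance is not excluded at a share of 0.05.

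The Hras effect differed between genotypes for 3342 genes, with Gabrp at -3.36, Sorbs2 at -3.21 and Il3 at -3.06 and list medians of 0.49 for the unfolded protein response, 0.43 for ERK targets, 0.80 for fibroblast markers and 0.64 for EGF receptor ligands. Of 100 splits 1, the real one, gave as many, a share under 0.05, and the highest other gave 2894. Here too the splits cannot test whether 2 real effects are equal. The sex-linked genes moved with this difference as well, so the makeup of the cultures cannot be told apart from it. In wild-type cells the GW0742 effect differed between Hras and mock cells for 492 genes, with Serpinb9e at 2.82, Mmp13 at 2.09 and Alox12b at 1.94 and list medians of -0.22 for cholesterol and sterol synthesis and 0.15 for EGF receptor ligands. As many genes passed in 5 of 100 splits, the highest other giving 1508, which over all splits again does not exclude chance at that share. The other splits that gave as many as the real one (1, 7, 0 and 4 for these differences in turn) all kept or exchanged the labels of one of the 2 effects whole, so they still held that effect. Among the 84, 82, 81 and 77 splits that broke both, 0 gave as many, and the highest counts were 1, 145, 0 and 0. Breaking both removes each effect along with the difference, so these splits do not test the difference alone.

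A signal also appeared in data outside the gene comparisons, in 13120 probe sets with either no gene symbol (11799) or several (1321). Of these, 1269 passed with Hras in wild-type cells and 41 with GW0742 in wild-type Hras cells. Of the 19937 genes tested, 7454 and 1219 passed in these comparisons.

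A first pattern was the 1001 genes called with GW0742 in null cells carrying Hras, where the receptor is targeted. Remaining receptor function would move the PPAR target list, whose median there was -0.0167 against 0.28 in wild-type Hras cells, and the test of the difference argues against it. With one of the 6 arrays left out the count was 393 at the lowest. This argues against a single outlying array as the source of all the calls. The count rose to 2539 without GW0742 replicate 1, so that array lowered the count. On the fourth principal component it lay at -6.03, nearer the DMSO arrays (-11.0 to -6.78) than GW0742 replicates 2 and 3 (8.46 and 10.7) did. Whether one array made part of the calls stays open, since 393 lay between the bounds set beforehand. An axis of variation between arrays of one group also stays open. The absolute correlation across genes of the change with the main axis within the wild-type Hras groups was 0.175. This value lay between the bounds set beforehand for and against such an axis. Within the null Hras GW0742 group, which had the widest spread, 76.8% of the deviations lay on its own main axis. That axis had an absolute correlation of 0.271 with the wild-type Hras axis. The group has too few arrays for its share to decide the question. Whether the change follows the group's own axis was not tested. With the real split giving 1001 genes and the highest other split of the same 6 arrays 845, and 10 splits too few for a share under 0.05, an effect of GW0742 without the receptor may be set beside these explanations only as a hypothesis.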

How the results depend on the processing

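The array weights and the model without the null Hras GW0742 group were chosen after the results were seen. Across the planned and added alternatives 0 calls of the genes named by the rule changed sign. Another probe set of a gene was counted as a changed sign only if it passed. Directions of lists and genes named outside the rule were not part of this check. With every probe set kept, 8 and 7 other genes for Hras in wild-type and null cells and 5 and 3 for genotype in mock and Hras cells had probe sets passing in both directions. With each array centred on its median, the 40% dimmest genes left out, every probe set kept, the replicate block, or without the null Hras GW0742 group, each total count of genes stayed within 1.5 times that reported. By direction some moved further: for positive GW0742 by genotype from 57 to 106 (dim genes left out) and 92 (group left out) in mock cells and from 103 to 63 (centred) in Hras cells, for negative GW0742 by Hras from 84 to 55 (centred), 127 (dim) and 131 (group), and for lower with GW0742 from 329 to 502 (dim) and 508 (group) in wild-type Hras and from 301 to 567 (dim) in null Hras cells. A minimum fold of 1.5, which by construction passes fewer genes, left 99, 294, 175, 2198, 2445, 334, 580, 78, 142, 983 and 212 for the comparisons in the order GW0742 in wild-type mock, wild-type Hras and null Hras cells, Hras in wild-type and null cells, genotype in mock and Hras cells, GW0742 by genotype in mock and Hras cells, Hras by genotype and GW0742 by Hras. With only the arrays compared, GW0742 counts were 775 in wild-type Hras cells and 0 in null Hras cells, the differences between genotypes 291 (mock) and 103 (Hras), and 6 lists passed for GW0742 in null mock cells. Trend and robust moderation gave 260 for GW0742 by genotype in mock cells and 6 lists for GW0742 in null mock cells, with 496 lower for GW0742 in null Hras cells and 133 negative for GW0742 by Hras. The array weights, whose estimation did not converge, ran from 0.219 to 4.61, both in the null Hras GW0742 group. They gave 1620, 1, 2015 and 5167 genes for GW0742 in wild-type mock, null mock, wild-type Hras and null Hras cells, 3164 for genotype in mock cells, 436, 1596 and 1198 for GW0742 by genotype in mock and Hras cells and GW0742 by Hras, and 5 lists for GW0742 in null mock cells. With an estimated correlation fewer of the 25 lists passed than at the preset one, whose counts are in brackets. For GW0742 (same order) they were 5 (12), 0 (2), 6 (11) and 3 (10), and for Hras 1 (17) and 3 (15). For genotype they were 6 (14) and 1 (11), and for GW0742 by genotype 4 (16) and 6 (15). Hras by genotype had 4 (12) and GW0742 by Hras 2 (16). For each moved value the cause was not tested, except for the minimum fold. Signal over background was not analysed here, so the effect of dim signal was checked only by leaving out the dimmest genes.

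Leaving out 1 array at a time gave, lowest to highest, 288 to 401 genes and 11 to 13 lists for GW0742 in wild-type mock cells, 0 to 2 genes and 0 to 7 lists in null mock cells, 821 to 1111 and 10 to 12 in wild-type Hras cells, and 393 to 2539 and 9 to 17 in null Hras cells. It gave 6642 to 6882 genes for Hras in wild-type and 7458 to 7800 in null cells, 1395 to 1904 for genotype in mock and 2849 to 3815 in Hras cells, 114 to 162 and 240 to 651 for GW0742 by genotype in mock and Hras cells, 2669 to 3549 for Hras by genotype, and 286 to 482 genes and 11 to 17 lists for GW0742 by Hras. Of 442 named calls 45 lost the threshold in some such refit and 0 changed sign. Replicate numbers did not clearly pair the arrays, though weak pairing is not excluded. The 84 same-number pairs had a median correlation of deviations of 0.0151 (-0.287 to 0.253). On average 12 of 24 arrays correlated best with their own number, and 1 of 28 group pairs had all correlations over 0.1. That pair was null against wild-type mock DMSO, with 2075 genes under the replicate block against 2076 without it. The block ended the calls of Krt10 (adjusted p = 0.0525) and Pparg (adjusted p = 0.0628) between null and wild-type cells, in mock and in Hras cells respectively, and gave 573, 0, 1278, 1086, 7423, 8137, 3882, 179, 336, 3371 and 567 genes elsewhere.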

Other observations

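In this part the 9 genes of the last pattern were chosen after the results were seen, and the test on their neighbours was set before its own result was seen. With Hras, cholesterol and sterol synthesis genes rose in 15 of 20 cases in wild-type cells (15 adjusted over the list alone, median 0.44, adjusted p = 6.15e-07, and adjusted p = 0.0911 with an estimated correlation) and 16 of 20 in null cells (16 adjusted over the list alone, median 0.38, adjusted p = 6.3e-07, and adjusted p = 0.0667 with an estimated correlation), with 1 falling in each. Mitochondrial fatty acid oxidation genes fell in 15 of 22 cases in wild-type cells (15 adjusted over the list alone, median -0.30, adjusted p = 0.00139, and adjusted p = 0.322 with an estimated correlation) and 16 of 22 in null cells (17 adjusted over the list alone, median -0.42, adjusted p = 6.3e-07, and adjusted p = 0.156 with an estimated correlation), while 4 and 1 rose. Cpt1a fell more in null (-1.85 ± 0.07) than in wild-type cells (-0.53 ± 0.07), with a difference of -1.32 ± 0.09 (adjusted p = 1.08e-08). Interferon response genes fell in 18 of 32 cases in wild-type cells and rose in 3 (18 and 3 adjusted over the list alone, median -0.56, adjusted p = 5e-05, and adjusted p = 0.222 with an estimated correlation). In null cells cell cycle genes rose in 27 of 38 cases and 0 fell (30 adjusted over the list alone, median 0.42, adjusted p = 6.85e-10, and adjusted p = 0.107 with an estimated correlation).

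Splits of the 6 arrays of each comparison number 10, too few for a share under 0.05. The real split and the highest other gave 570 and 0 genes for GW0742 in wild-type mock cells, 0 and 0 in null mock cells (10 of 10 splits as many), 1219 and 0 in wild-type Hras cells, 7454 and 0 for Hras in wild-type cells, 8119 and 0 in null cells, 2076 and 0 for genotype in mock cells and 3871 and 128 in Hras cells. Each of these had 1 split as large, the real one, except in null mock cells. In the other splits a real difference between the groups enters the spread and so lowers their counts. Any sizeable difference would do this, whatever its cause, so low counts there do not tell one cause from another.

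A second pattern was the genotype differences, which had a correlation of -0.02 across genes between mock and Hras cells. DNA linked to the targeted locus would enrich calls among the 200 genes nearest Ppard. The odds ratio was 0.797 in mock cells (17 of 200) and 1.10 in Hras cells (42 of 200). No enrichment passed there by a one-sided Fisher exact test (p = 0.844 and 0.312). These 200 genes are far fewer than the calls, so the test cannot weigh linked DNA as the whole cause. Linked DNA acting on genes elsewhere was not tested. Sex-linked RNA did differ between the genotypes. In mock cells all 4 genes passed, with Xist opposite to the Y-linked genes, and in Hras cells the Y-linked genes passed and Xist did not. The median absolute difference of the 4 genes was 0.321 in mock cells, where the largest replicate SD was 0.199. In Hras cells it was 0.445, where that SD was 0.116. How many of the calls a different sex makeup of the mice the cells came from accounts for stays open. The Y-linked genes were higher in null mock and lower in null Hras cells. The cell preparations of the 4 kinds of culture may therefore have differed in makeup. Preparation and genotype cannot be told apart here, and neither can preparation and Hras in null cells. A biological difference between genotypes is untested beyond these comparisons.

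A further pattern was 9 genes that differed by over 2-fold the same way between null and wild-type cells in all 4 combinations of virus and ligand, chosen after their values were seen. Ublcp1 (-3.35 to -2.81), Mcam (-3.23 to -1.78), Mid1 (-2.75 to -1.01) and Klk9 (-1.80 to -1.14) were lower in null cells, and Spon2 (2.17 to 2.65), Dhdh (up to 1.99), Atp10d (1.34 to 1.94), C330024D21Rik (1.39 to 1.75) and Abca5 (1.01 to 1.36) were higher. The values argue against linked DNA acting on genes close to Ppard, since 0 of the 9 lay among the 100 genes on either side of it. DNA of another strain in blocks along the chromosomes stays open: 2 of the 9 had another of them within 20 neighbouring genes, and 7.26% of 10000 random draws gave as many, with a median of 0. A constant effect of the genotype itself may be an alternative, and was not tested.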
